A study of Homo sapiens with 28 samples.

How the data were processed

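RNA was measured in 20 libraries of the human non-small-cell lung cancer lines H2009 and H596, and RUVBL1 or RUVBL2 cDNA was sequenced in 8 further libraries of H2009 cells. Per the submitters' processing notes, RNA reads were processed with CASAVA 1.8.2, TopHat2 2.0.12 and Cufflinks 2.2.1 on the hg19 build, and the cDNA reads with BWA 0.7.15 and SAMtools. The RNA values are FPKM per gene as the authors deposited them, in 3 tables: one for both compounds in both lines (13481 genes, 12 libraries), one for the siRNA in H2009 (4 libraries) and one for the siRNA in H596 (12384 genes, 4 libraries). The tables may have been normalized separately, so tests were made only within a table. These files give no read depth, so the depth behind an FPKM value is unknown. Of 12087 entries in the H2009 siRNA file, 19 carry gene names that a spreadsheet had turned into dates; they were left out because they name no gene. The cDNA files hold counts per cDNA position, deposited without normalization, of reads with a base other than the reference; the count of the reference base is 0 at every position, so depth and allele shares are unknown. Inserted and deleted bases were not used here. The bases are counted in upper-case and lower-case columns, which were added together; what the case marks is not given in the sources used here.

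Differences in RNA were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation along a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Genes with near-identical copies, such as histone genes, can share reads, so their values are uncertain. A fold change on this scale understates the change of genes with low FPKM. Genes entered the test with a mean FPKM of at least 1 over the libraries, in the compound table over the 6 libraries of at least 1 line; this left 12781 genes for the compounds, 11223 for the siRNA in H2009 and 12004 in H596. The compound table was fitted with all 12 libraries and 6 group means. Lists of genes were tested with camera at a preset correlation of 0.01, with adjustment over the lists that had at least 5 measured members. There were 29 lists and 231 tests of a list in a comparison. Of these, 88 passed at the preset correlation and 0 with a correlation estimated from the data, where the smallest adjusted p was 0.0653. Every list call below therefore rests on the preset value. With so few libraries the test with an estimated correlation could hardly pass, above all for the siRNA. Failing it does not show that a list did not change. The tests, lists, rule for naming genes and most alternatives were fixed before the data were examined. Chosen later were the test of the cDNA counts, the use of the rule on the paired fit, and the alternatives without genes listed at 0, with 1 relative depth per library, and with a second change on top of the replicate block. The rule takes RUVBL1 and RUVBL2, the 8 highest and 8 lowest fold changes among called genes whose treated libraries all lie beyond the controls, and up to 3 members of each called list; for cDNA alleles it takes the 10 with the highest mean depth-scaled count, in place of the share first planned.

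Libraries with the same replicate number resembled each other. The difference between replicate 1 and replicate 2 across genes correlated between groups in all 45 pairs of the 10 groups, with r from 0.459 to 0.966, also between cell lines. The labels do not say what a number marks, and each comparison has only 2 numbers. A fit with the replicate number as a block, called the paired fit here, was among the alternatives fixed in advance. The correlations and the counts of calls from both fits were then seen together, so the judgement that the numbers pair the libraries was not made blind to the counts. For that reason the unpaired fit remains the result of each comparison, and the paired fit stands beside it. Genes named in the siRNA comparisons and in H596 with compound B come from applying the same rule to the paired fit, a step chosen after the counts had been seen. The fold changes are identical in both fits and only the errors differ. Each SE given below is that of the unpaired fit, also where a paired adjusted p stands beside it. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries.

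The fits were tested on simulated data made from the replicate structure of each table, which assumes that the replicate difference is additive. The data were drawn from the paired fit itself, with independent normal noise of its own size. They therefore favour the paired fit by construction and do not show that it suits the real libraries. For the H2009 siRNA table (11223 genes) the unpaired fit called 0 of 100 genes changed by 2 on the log2 scale, and the paired fit called 100 of 100 with 23 unchanged genes called in all. For the H596 siRNA table (12004 genes) the counts were 0 and 100 of 100, with 8 unchanged genes called by the paired fit. For compound B in H2009 (12781 genes) the unpaired fit called 79 of 100 genes changed by 2 and 24 of 100 changed by 1, and the paired fit called 100 of 100 at both sizes, with 9 unchanged genes called.

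For the cDNA counts, a Fisher test on allele shares had been planned and could not be made without depth. Each count was instead compared with the count in the library without doxycycline, scaled by a relative depth. The relative depth of a library was the median count ratio of mismatches with at least 20 reads in the library without doxycycline, within 75 positions on either side. One ratio per library was tried first; the local one was chosen after the ratio was seen to vary along the RUVBL2 cDNA, from 0.5 to 2.76 in replicate 1. An allele was called when, in all 3 selected libraries, the depth-scaled count was at least 500, the ratio at least 3 and the one-sided exact binomial test passed 0.05 after Benjamini-Hochberg adjustment. Counts below 3 without doxycycline were set to 3. Planned settings on allele shares could not be applied. With 1 library without doxycycline, this test compares libraries, not conditions. Reads are not independent molecules, so it covers counting error only. Simulated counts had counting error only, and alleles were raised alike in all 3 libraries. Raised alleles were drawn from the more abundant ones, which leaves out alleles such as I326M of RUVBL1, called with 38 reads without doxycycline. For RUVBL1 (4155 alleles), 19 of 20 raised 5-fold and 20 of 20 raised 20-fold were called, with 0 of 4115 unchanged alleles. For RUVBL2 (4533 alleles) 20 of 20 were called at both sizes and 0 of 4493 unchanged alleles. These rates do not cover rarer alleles or further differences between libraries.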

Results

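RUVBL1 and RUVBL2 are AAA+ ATPases that act together as chaperones of large complexes. The series measured RNA after knockdown of RUVBL1 by siRNA against a non-targeting siRNA, for 2.5 days in H2009 and 3 days in H596, with 2 libraries per group. It also measured RNA after 24 h with 100 nM of compound B or compound C, known here only by these names, against untreated cells, with 2 libraries per group and line. H2009 cells carrying doxycycline-inducible RUVBL1 or RUVBL2 cDNA mutated by PCR were sequenced without doxycycline (1 library per gene) and with doxycycline after about 1 month in 500 nM compound B (3 libraries per gene). The sum of non-reference base counts per library ranged from 213855 to 1842067.

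RUVBL1 lay below the controls in all 4 libraries with the siRNA. In H2009 the mean was 1.43 FPKM with the siRNA and 76.0 FPKM without, a log2 change of -4.98 (SE 0.34, n = 2), and within replicates 1 and 2 it was -5.01 and -4.95. In H596 the means were 2.39 and 117.6 FPKM, a log2 change of -5.13 (SE 0.22, n = 2). Neither passed adjustment in the unpaired limma fit (adjusted p = 0.56 and 0.158); in the paired fit both did (1.95e-07 and 2.25e-08). RUVBL2 differed by 0.07 (SE 0.29) in H2009 and -0.23 (SE 0.29) in H596 on the log2 scale, and only the H596 value passed in the paired fit (adjusted p = 0.00213).

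**Figure D1:**
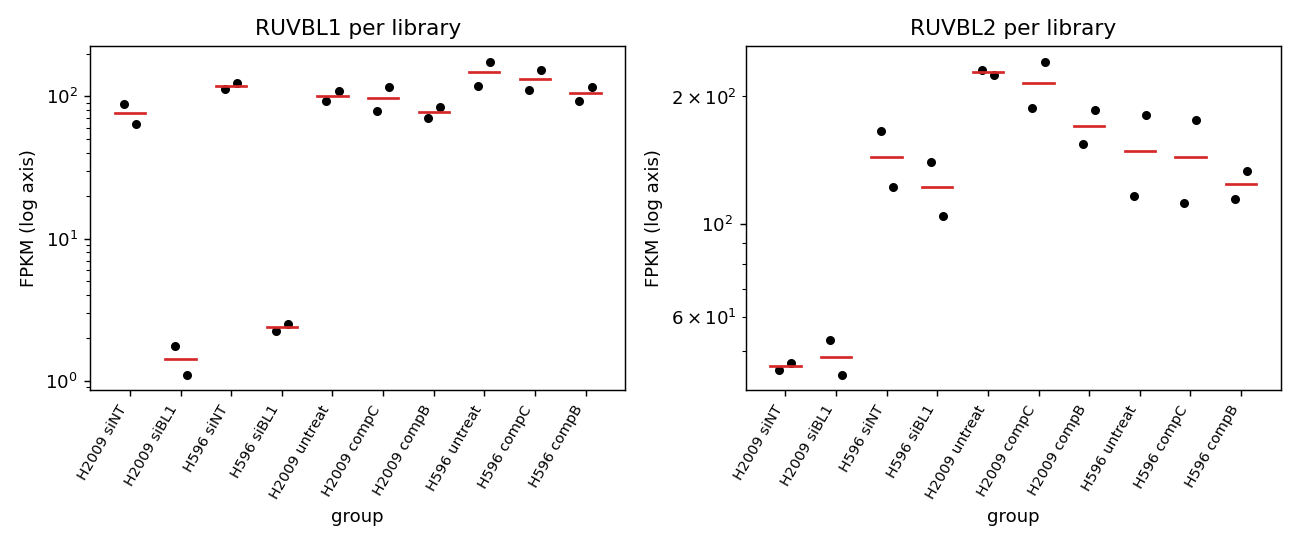
FPKM of RUVBL1 and RUVBL2 in each library on log axes, by group; points are the 2 libraries and red lines their mean. RUVBL1 lies at 1.43 FPKM on average with the siRNA in H2009 and at 76.0 without.

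In H2009, the unpaired fit called 0 of 11223 genes after the siRNA, with 532 at an unadjusted p under 0.05, and the paired fit called 1733 higher and 3025 lower. The 532 are fewer than a share of 0.05, which unchanged genes would give in a calibrated test. The unpaired fit leaves the replicate difference in its error, so its 0 calls do not show that no gene changed. The values that follow are log2 changes, none of which passed the unpaired fit. Histone genes were among the highest: HIST1H2BD was at 2.52 (SE 0.35; 2.32 and 2.73 within replicates 1 and 2; paired adjusted p = 7.8e-05) and HIST1H2BK at 1.96 (SE 0.59). Of 11 measured replication-dependent histone genes, 10 passed as higher in the paired fit, 2 as higher when adjusted over the list alone in the unpaired fit, and the list passed the preset test (adjusted p = 1.62e-12, and adjusted p = 0.379 with an estimated correlation). Among the lowest were ANKRD1 (-2.38, SE 0.29), DTNBP1 (-2.18, SE 0.46), PROSC (-2.04, SE 0.29) and the interferon-induced gene IFI44 (-1.88, SE 0.44). The ribonucleotide reductase subunit RRM2 was at -1.84 (SE 0.58) and the CTP synthase gene CTPS1 at -1.54 (SE 0.44); 16 of 21 nucleotide synthesis genes passed as lower in the paired fit and 0 in the unpaired fit, and the list passed the preset test (adjusted p = 2.2e-05, and adjusted p = 0.676 with an estimated correlation). Of 48 DNA replication genes 27 passed as lower and 2 as higher in the paired fit, among the lower CDC45 (-1.25, SE 0.37) and MCM7 (-1.13, SE 0.46), with a preset adjusted p = 0.00143 and adjusted p = 0.676 with an estimated correlation. Of 17 interferon response genes 8 passed as lower and 1 as higher in the paired fit, and the list's median was -0.30 (preset adjusted p = 0.0246, 0.0881 in the paired fit, and adjusted p = 0.676 with an estimated correlation). Of 44 genes of small nucleolar ribonucleoproteins and ribosomal RNA processing, 17 passed as lower and 1 as higher in the paired fit. By camera the list had a preset adjusted p = 0.0304, and adjusted p = 0.742 with an estimated correlation. Of 20 cytosolic heat shock genes 12 passed as lower in the paired fit. By camera that list had 0.0246 and 0.676. Adjusted over the list alone, 0 genes of the nucleotide synthesis, replication, interferon, ribonucleoprotein and heat shock lists passed the unpaired limma fit. With quantile normalization the paired fit called 2923 genes higher and 2845 lower, so the excess of lower calls depends on the scaling: 36.4% of the paired calls were higher without it and 50.7% with it.

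In H596, the unpaired fit called 0 of 12004 genes after the siRNA, with 137 at an unadjusted p under 0.05. The 137 are again fewer than a share of 0.05, so the 0 calls do not show that no gene changed. The paired fit called 2377 higher and 3197 lower, or 2654 higher and 2715 lower with quantile normalization. The values that follow are log2 changes that did not pass the unpaired fit. The chemokine genes CCL20 and CXCL8 were at 1.89 (SE 0.33; 1.90 and 1.88 within replicates 1 and 2) and 1.65 (SE 0.42). The interferon-induced genes IFI27, IFI6 and IFI44L were at 2.28 (SE 0.72), 1.84 (SE 0.69) and 1.66 (SE 0.27); 23 of 30 measured interferon response genes passed as higher and 1 as lower in the paired fit, 2 as higher when adjusted over the list alone in the unpaired fit (preset adjusted p = 5.09e-17, and adjusted p = 0.216 with an estimated correlation). All 40 measured genes of mitosis passed as lower in the paired fit and 0 in the unpaired fit, with CDC20 at -0.82 (SE 0.31) and the kinase PLK1 at -0.87 (SE 0.37); the list passed the preset test (adjusted p = 4.12e-27, and adjusted p = 0.173 with an estimated correlation). Of 44 genes of small nucleolar ribonucleoproteins and ribosomal RNA processing, 32 passed as lower and 1 as higher in the paired fit, with NHP2 at -0.80 (SE 0.42) and a preset adjusted p = 1.81e-07 (adjusted p = 0.173 with an estimated correlation). Of 17 targets of the inflammatory transcription factor NF-kappa B 14 passed as higher and 1 as lower in the paired fit, with a preset adjusted p = 5.94e-11 and adjusted p = 0.173 with an estimated correlation. Of 21 cytosolic heat shock genes 19 passed as lower in the paired fit, with a preset adjusted p = 2.72e-05 and adjusted p = 0.173 with an estimated correlation. Of 19 replication-dependent histone genes 5 passed as higher and 5 as lower in the paired fit, and the list, with a median of 0.02, did not pass (preset adjusted p = 0.581). The full list holds 30 genes, with 19 measured here and 11 in H2009, so the results of the 2 lines are not over the same genes. Of 21 nucleotide synthesis genes 17 passed as lower in the paired fit. By camera the list had a preset adjusted p = 1.81e-07, and adjusted p = 0.173 with an estimated correlation. Of 48 DNA replication genes 34 passed as lower and 1 as higher in the paired fit. By camera that list had 2.95e-06 and 0.173. Adjusted over the list alone, 0 genes of the mitosis, ribonucleoprotein, NF-kappa B, heat shock, histone, nucleotide synthesis and replication lists passed the unpaired limma fit. The time after the siRNA differed between the lines, and no test of the difference between lines was made for the siRNA.

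Compound B changed 1455 of 12781 genes in H2009, 813 higher and 642 lower. The cell cycle inhibitor CDKN1A rose from 3.95 to 33.4 FPKM, a log2 change of 2.83 (SE 0.38, n = 2, adjusted p = 0.00224), GADD45A by 2.76 (SE 0.29, adjusted p = 0.000849) and the stress-induced transcription factor gene ATF3 by 2.82 (SE 0.22, adjusted p = 0.000182). The connective tissue growth factor gene CTGF rose by 2.78 (SE 0.34) and ID2 by 2.60 (SE 0.18). The small nuclear RNA gene RNU12 was listed at 6.55 and 7.01 FPKM with compound B and at 0 in both untreated libraries, which passed (adjusted p = 0.0317). With compound C it was listed at 7.95 and 0 FPKM, and compound B against compound C did not pass for it (adjusted p = 0.274, paired 0.0674). The connexin gene GJA1 fell by 2.25 (SE 0.20, adjusted p = 0.00032) and the RNA-binding protein gene HNRNPD by 2.16 (SE 0.28). The helicase gene DDX39A was at -2.20 (SE 0.46). MYBPH fell by 2.78 (SE 0.23), FGFBP1 by 2.50 (SE 0.22) and the interferon-induced gene IFI44 by 2.37 (SE 0.29). Of 26 measured p53 target genes 6 rose and 0 fell; adjusted over the list alone, 10 were higher and 3 lower (preset adjusted p = 0.00382, and adjusted p = 0.128 with an estimated correlation). Of 22 histone genes 13 rose and 0 fell, with HIST2H2BE at 2.27 (SE 0.26); adjusted over the list alone 14 were higher (preset adjusted p = 1.43e-09, and adjusted p = 0.0653 with an estimated correlation). Of 21 nucleotide synthesis genes 5 fell and 1 rose, with PFAS at -1.92 (SE 0.23); adjusted over the list alone 9 were lower and 1 higher (preset adjusted p = 0.000499, and adjusted p = 0.0653 with an estimated correlation). Of 28 partners in chromatin remodelling complexes 5 fell, and 5 were lower adjusted over the list alone, among them the acetyltransferase gene KAT5 (-2.04, SE 0.17) and ING3 (-1.75, SE 0.23), with a preset adjusted p = 0.000987 and adjusted p = 0.0653 with an estimated correlation. Of 40 genes of mitosis 7 fell, and 8 were lower adjusted over the list alone, with CDC20 at -1.11 (SE 0.20) and PLK1 at -1.29 (SE 0.28), with a preset adjusted p = 0.000731 and adjusted p = 0.446 with an estimated correlation. Of 44 genes of small nucleolar ribonucleoproteins and ribosomal RNA processing 7 fell, and 12 were lower adjusted over the list alone, with a preset adjusted p = 2.87e-07 and adjusted p = 0.342 with an estimated correlation. In the paired fit, 17 p53 target genes passed as higher and 5 as lower, 17 histone genes as higher and 1 as lower, 14 nucleotide synthesis genes as lower and 1 as higher, and 11 chromatin remodelling partners as lower and 1 as higher. It also called 20 genes of mitosis lower and 1 higher, and 32 ribonucleoprotein genes lower and 1 higher. RUVBL1 itself differed by -0.39 (SE 0.29, adjusted p = 0.448), and passed as lower in the paired fit (adjusted p = 0.0492, 95% interval -0.71 to -0.07). The paired fit called 2833 genes higher and 2863 lower, and the fit of the 6 H2009 libraries alone called 536, 371 higher and 165 lower. The balance of higher and lower calls therefore depends on the fit. Without replicate 1 or 2 of compound B the count was 353 or 639, and without replicate 1 or 2 of the untreated cells 660 or 595.

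**Figure D2:**
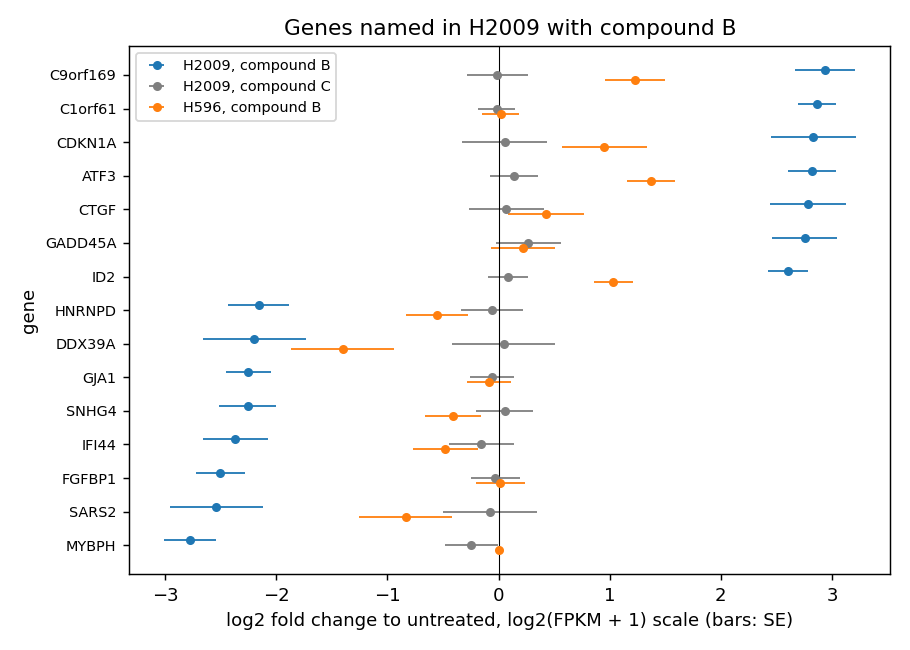
Log2 fold change to untreated cells, on the log2(FPKM + 1) scale, of the genes named in H2009 with compound B except RNU12, which is listed at 0 in the controls; bars are the SE of the unpaired fit, and MYBPH is listed at 0 in H596 with compound B and without treatment. GJA1 and C1orf61 also lay under 0.5 FPKM in H596 with compound B and without treatment, so the H596 points of these genes say little of a response. CDKN1A lies at 2.83 with compound B and at 0.05 with compound C in H2009.

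With compound C at the same dose and time in H2009, the unpaired limma fit had 9 genes at an unadjusted p under 0.05. That is fewer than a share of 0.05 of the genes tested, and 1 gene was called. That gene, EEF1A1, is listed at 0 in both compound C libraries and at 1962 FPKM or more in the other libraries of the compound table, and without genes listed at 0 in any library the count was 0. The paired fit also called FAM72D, one of a family of near-identical genes, at 4.00 FPKM with compound C and 0.00555 without (adjusted p = 0.000216). For CDKN1A the log2 change with compound C was 0.05 (95% interval -0.80 to 0.91), for ATF3 0.14 (-0.35 to 0.62) and for GJA1 -0.06 (-0.50 to 0.39). The direct comparison of compound B with compound C in H2009 called 787 genes higher and 675 lower with compound B. CDKN1A was higher by 2.78 (SE 0.38, 95% interval 1.92 to 3.64) and GJA1 was at -2.19 (SE 0.20). In that comparison the paired fit called 2763 higher and 3066 lower. The fit of the H2009 libraries alone called 514, and the count was 345 or 579 without replicate 1 or 2 of compound B and 692 without replicate 2 of compound C. The median 95% interval of compound C against untreated cells spanned 0.565 on either side of the estimate in the unpaired fit and 0.299 in the paired fit. Of 44 genes of small nucleolar ribonucleoproteins and ribosomal RNA processing 0 passed the limma test with compound C, also adjusted over the list alone, and their median log2 change was -0.08 (preset adjusted p = 0.00219, and adjusted p = 0.976 with an estimated correlation). The other lists that passed the preset test, all as lower and with the same adjusted p = 0.976 with an estimated correlation, were U5 small nuclear ribonucleoprotein and cofactors (median -0.14, adjusted p = 0.0018), PIKK kinases with their partners and TTT chaperone (-0.11, adjusted p = 0.0306) and mesenchymal genes (-0.06, adjusted p = 0.0306).

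In H596, compound B gave 0 calls in the unpaired limma fit, with 735 genes at an unadjusted p under 0.05; the paired fit called 484 higher and 369 lower. Log2 changes that did not pass the unpaired fit included HIST1H2BF at 1.38 (SE 0.22; 1.08 and 1.67 within replicates 1 and 2), TP53INP2 at 1.48 (SE 0.50), HHLA3 at 1.44 (SE 0.20), DDX39A at -1.40 (SE 0.46) and CDC20 at -1.03 (SE 0.20). Of 40 genes of mitosis 6 passed as lower in the paired fit, 0 in the unpaired fit and 1 adjusted over the list alone (preset adjusted p = 1.26e-08, and adjusted p = 0.202 with an estimated correlation). Of 22 histone genes 9 passed as higher and 1 as lower in the paired fit, 8 as higher when adjusted over the list alone in the unpaired fit (preset adjusted p = 7.2e-08, and adjusted p = 0.0837 with an estimated correlation). Of 44 genes of small nucleolar ribonucleoproteins and ribosomal RNA processing 7 passed as lower in the paired fit (27 adjusted over the list alone) and 0 in the unpaired fit, also adjusted over the list alone, with a median of -0.43 (preset adjusted p = 8.88e-11, and adjusted p = 0.202 with an estimated correlation). In compound B against compound C in H596, 0 of these genes passed either fit, also adjusted over the list alone. Their median was -0.24 (preset adjusted p = 4.06e-05, and adjusted p = 0.595 with an estimated correlation).

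Compound C gave 0 calls in H596 in both limma fits. In the unpaired and paired fit, 20 and 182 genes had an unadjusted p under 0.05, both under a share of 0.05 of the genes tested. Even so, 7 of 26 lists passed the preset test. The median log2 change of the ribonucleoprotein and ribosomal RNA processing genes was -0.18 (preset adjusted p = 9.26e-12, and adjusted p = 0.467 with an estimated correlation), and that of squamous lineage genes -0.20 (3.73e-07, and adjusted p = 0.147 with an estimated correlation). It was -0.19 for MYC-driven growth genes (0.000237, and adjusted p = 0.31 with an estimated correlation), -0.14 for cytosolic heat shock genes (0.000323, and adjusted p = 0.554 with an estimated correlation) and -0.13 for NF-kappa B targets (0.00322, and adjusted p = 0.561 with an estimated correlation). Histone genes, at 0.05, and interferon response genes, at 0.04, passed as higher (both 0.0124, and adjusted p = 0.554 and 0.873 with an estimated correlation). In these 7 lists 0 genes passed either fit over all genes, and 0 passed the unpaired fit adjusted over the list alone. In the paired fit adjusted over the list alone 2 squamous lineage genes passed as lower, the keratin genes KRT14 (-0.55, SE 0.22) and KRT6A (-0.42, SE 0.18). Both were named after their values were seen. Compound B against compound C called 1 gene in H596, the ribonuclease gene RNASE7, higher by 1.45 (SE 0.15, adjusted p = 0.0489); the paired fit called 382 higher and 213 lower, and with a pseudocount of 0.1, or with any 1 library of the pair of groups left out, the unpaired count was 0.

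The effect of compound B differed between the lines for 58 genes, 16 with a higher and 42 with a lower log2 change in H596 than in H2009, and the paired fit called 781 and 1047, or 1115 and 1129 with quantile normalization. The difference, H596 minus H2009, was -2.54 (SE 0.41, adjusted p = 0.0439) for GADD45A, which stood at 60.5 FPKM in untreated H596 and 8.10 FPKM in untreated H2009, and -2.32 (SE 0.37) for the receptor gene FGFR3, at 10.9 and 0.332 FPKM. It was 2.52 (SE 0.31) for FGFBP1, at 180.4 and 8.89 FPKM. The acetyltransferase gene KAT5 differed by 1.47 (SE 0.23, adjusted p = 0.0439). Of the 16 genes with the largest called differences, 8 in each direction, 10 were under 0.5 FPKM in all 4 H596 libraries compared, among them GJA1 (2.17, SE 0.28), the intermediate filament gene VIM (1.97, SE 0.25) and TEX14 (-2.24, SE 0.14). The count was 8 to 31 when any 1 of the 8 libraries was left out, and 14 without genes listed at 0. With a higher change in H596, 0 genes were called in place of 16 without replicate 1 of compound B in H2009, replicate 1 or 2 of compound B in H596 or replicate 1 of untreated H596. There was 1 without replicate 2 of untreated H596. There were 4 without replicate 2 of compound B in H2009, and 9 or 4 without replicate 1 or 2 of untreated H2009.

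Across genes, which are not independent replicates, the changes after the siRNA and with compound B correlated with Spearman's rho 0.531 in H2009 over 11074 genes and 0.392 in H596 over 11695 genes. The 2 comparisons share no library. Within replicate 1 and within replicate 2 rho was 0.492 and 0.442 in H2009 and 0.283 and 0.409 in H596. With replicate 1 of the siRNA set against replicate 2 of compound B and the reverse, it was 0.529 and 0.514 in H2009 and 0.411 and 0.226 in H596. Calls of the paired fit overlapped in H2009 for 929 higher genes, where independent lists would share 362.9, and for 1459 lower genes against 729.2. In H596 the overlaps were 179 against 79.2 and 203 against 97.7. Between lines rho was 0.456 for the siRNA and 0.587 for compound B; these were 4 relations in all.

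With doxycycline and compound B, 33 of 4155 RUVBL1 alleles were enriched in all 3 libraries against the library without doxycycline. Doxycycline, compound B and about 1 month of selection came together, so the enrichment cannot be assigned to any one of them. Of the 33, 28 change an amino acid, 5 do not and 0 make a stop. Of the 4155 tested, 3007 change an amino acid, 933 do not, 164 make a stop and 51 lie outside the coding sequence. The split by kind was not tested. The tested alleles are all base changes possible at the positions read, whether or not the mutated cDNA carried them. Their split is therefore not the make-up of that cDNA, and the 0 stops do not show selection against stops. Base positions count from 1 at the start of the sequenced cDNA and residues from the start methionine. P296S (C899T) had the highest mean depth-scaled count, with 830 reads without doxycycline and 63546 in replicate 1, and its ratios were 84.7, 86.4 and 105.8 in the 3 libraries. K265E (A806G) had ratios of 95.4, 94.9 and 117.4, L354Q (T1074A) of 122.9, 116.1 and 146, and R317Q (G963A) of 66.2, 44.6 and 105.7. A62T (G197A) had ratios of 37.1, 42.0 and 22.3, D273N (G830A) of 29.5, 24.3 and 31.1, and G63E (G201A) of 66.1, 42.7 and 32.0. E310G (A942G) had ratios of 28, 66.8 and 113.2 and M455I (G1378A) of 23.4, 13.0 and 18.8. The synonymous change E432E (G1309A) had ratios of 13.9, 9.89 and 21.6. The Walker A motif spans residues 70 to 77 and the Walker B motif begins at residue 302. In all 3 selected libraries, 31 of the 33 alleles had at least 99% of their reads in one letter case of the per-base counts, as had 49.4% of 1072 other RUVBL1 alleles with at least 100 reads. The counts of P296S and K265E kept a ratio of 1.34, 1.35 and 1.35 in the 3 libraries.

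For RUVBL2, 6 of 4533 alleles were enriched in all 3 libraries, and the enrichment cannot be assigned to doxycycline, compound B or time in culture here either. Of the 6, 4 change an amino acid and 2 do not. Of the 4533 tested, 3018 change an amino acid, 1014 do not, 135 make a stop and 366 lie outside the coding sequence. As for RUVBL1, these are base changes listed whether or not the mutated cDNA carried them. G266R (G853A) had ratios of 145.2, 55.2 and 10.1, E267V (A857T) of 13.5, 56.1 and 201.3, I202T (T662C) of 9.62, 41.2 and 148.6 and D319G (A1013G) of 5.18, 18.7 and 62.7. The synonymous changes D305D (C972T) and E112E (G393A) had ratios of 171.6, 61.7 and 10.1, and of 9.26, 4.78 and 139.7. Replicate 2 was the shallowest library, with relative depths of 0.155 to 0.386, and E112E passed there with 254 reads, scaled to 678. With a ratio of at least 10 in at least 1 library there were 27 alleles, 18 of them in 1 library alone. E267K (G856A) had a ratio of 245 in replicate 3 and 1.11 in replicate 1, and K365E (A1150G) ratios of 106.5 and 328.1 in replicates 1 and 2 and 1.00 in replicate 3. These 2 were chosen after their values were seen. Over the 3 libraries the log2 ratio of counts varied by 0.048 between G266R and D305D and by 0.055 to 0.107 among E267V, I202T and D319G, and by 3.42 to 8.53 in the other 11 of the 15 pairs. All 6 enriched RUVBL2 alleles had at least 99% of their reads in one letter case, as had 51.4% of 451 other alleles with at least 100 reads.

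**Figure D3:**
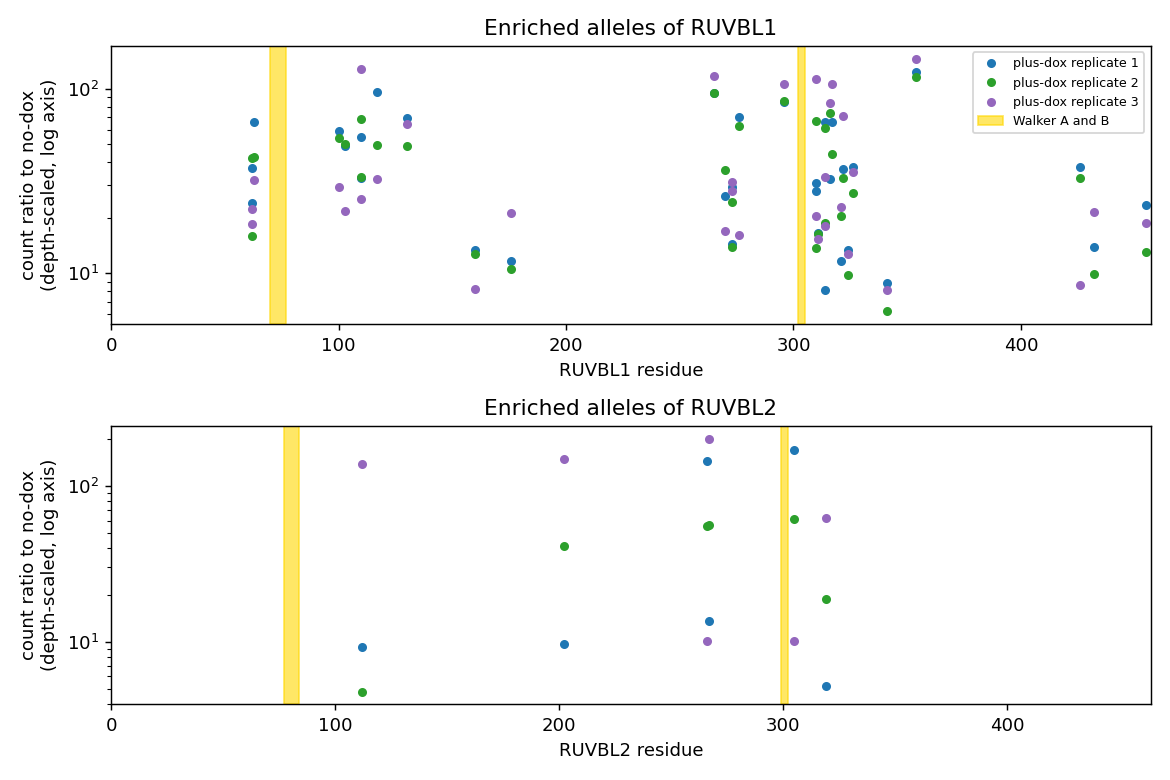
Depth-scaled count ratio to the library without doxycycline, on a log axis, of each called allele by residue, with a point per selected library and the Walker A and B motifs shaded. P296S in RUVBL1 lies between 84.7 and 105.8, and E112E in RUVBL2 between 4.78 and 139.7.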

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

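Every test of an explanation in this part was chosen after the result was seen, except the test of gene span.

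The effect of compound B differed between H596 and H2009 for 58 genes by a test of the difference in one fit, in which 10 of the 16 genes named were under 0.5 FPKM in all 4 H596 libraries. Beyond GJA1 (2.17), VIM (1.97), GADD45A (-2.54), FGFR3 (-2.32) and TEX14 (-2.24), the difference in log2 change was 2.78 for MYBPH, 2.52 for FGFBP1, 2.04 for MMP13, 1.804 for SFTA3, 1.65 for SDPR and 1.63 for PRICKLE1. It was -2.85 for C1orf61, -2.42 for C2orf78, -2.15 for RND1, -2.15 for NPTX2 and -2.12 for SLC26A2. The median difference of the lists that passed at the preset correlation was -0.99 for histones, -0.52 for cholesterol synthesis, -0.34 for p53 targets and -0.29 for endoplasmic reticulum chaperones. It was 0.51 for lung lineage genes, 0.41 for axonemal dyneins, 0.38 for the R2TP complex, 0.31 for nucleotide synthesis, 0.24 for DNA replication, 0.19 for small nucleolar ribonucleoproteins, 0.11 for chromatin remodelling partners and 0.11 for the interferon response. The lung lineage list had 5 measured genes of 13, and the axonemal dyneins 6 of 23. FPKM levels of list members were not compared between the lines, so a list difference can also come from genes near 0 in either line. None of these lists passed with an estimated correlation, and the axonemal dyneins did not pass with the replicate block.

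Replicate 1 and replicate 2 differed alike in all 10 groups. Differences between cultures that arose in each line on its own would give no correlation between lines, and the median r between lines was 0.636. That correlation was already part of the pattern, and differences between cultures shared by both lines were not tested. A library batch shared by both lines remains a candidate explanation, with a lowest r between lines of 0.459, but that correlation is the pattern itself and the labels do not say what a number marks. A bias that follows gene span was neither excluded nor borne out, since the correlation with span was -0.276 over 11866 genes, between the bounds of 0.1 and 0.3 set before the test. No biological explanation was tested.

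After the siRNA, 7 genes other than RUVBL1 were at least 2-fold lower in both lines in the paired fit. Of these, 3 were also called lower with compound B in H2009 and 1 in both lines, INSIG1, while PROSC was called higher with compound B in H2009 (0.48, adjusted p = 0.0173) and 0 were in H596. Loss of RUVBL1 function and targets of the siRNA other than RUVBL1 may both contribute and cannot be told apart, because the compound was given for 24 h and the siRNA for 2.5 or 3 days and the siRNA sequence was not used here.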

How the results depend on the processing

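The alternatives without genes listed at 0, with 1 relative depth per library, and those combined with the replicate block were chosen after seeing the data; settings on allele shares were not run because depth is unknown. The cause of each change was not tested. With the replicate block (the paired fit), the calls were 4758 after the siRNA in H2009 and 5574 in H596, 5696 for compound B and 2 for compound C in H2009, 5829 for compound B against C in H2009, 853 for compound B in H596, 595 for compound B against C in H596 and 1828 for the difference between lines. The block moved neither the 0 calls for compound C in H596 nor the called lists by over 1.5 times (91 against 88).

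The fit of one line alone gave 536 for compound B and 514 for compound B against C in H2009, and 0 for compound B against C in H596. That H596 count was also 0 with pseudocount 0.1, no filter, no trend and no genes listed at 0. Compound C in H2009 gave 2 calls with pseudocount 0.1 and 0 without genes listed at 0, and 1 in the paired fit without them. Compound B in H596 gave 6 calls with quantile normalization. The difference between lines gave 12 calls with pseudocount 0.1, 102 with no filter, 110 with quantile normalization, 29 with no trend and 14 with no genes listed at 0. With an estimated correlation 0 lists passed. For the siRNA in the 2 lines rho was 0.486 over genes with a mean FPKM of at least 5. With a depth-scaled count of at least 2000, 20 RUVBL1 and 2 RUVBL2 alleles were enriched, and with a ratio of at least 10, 3 RUVBL2 alleles.

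Leaving out each library in turn, with the lone sample of a group assumed to vary like the others, gave 1 to 12 calls after the siRNA in H2009 and 4 to 8 in H596, 353 to 660 for compound B and 1 to 2 for compound C in H2009, 345 to 1634 for compound B against C in H2009, 0 to 1 for compound B and 0 for compound B against C in H596, and 8 to 31 for the difference between lines. For RUVBL1 it gave 33 to 36 alleles and for RUVBL2 6 to 9. An allele had to pass in every library kept, so these counts could not fall and do not test dependence on a single library. Over the genes named and their alternatives, 0 results turned direction among genes that the unpaired fit called. A change of direction was not counted for genes that it did not call. Of 5533 results, 4923 were counted as staying on their side of the threshold, including any such uncounted changes of direction.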

Other observations

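Every test in this part was chosen after the result was seen. In the paired fits, 76 genes were called higher and 120 lower in all 4 of the comparisons of the siRNA and of compound B with their controls in both lines, among 10300 genes tested in all 4. DDX39A had log2 changes of -0.79 and -0.92 after the siRNA and -2.20 and -1.40 with compound B in H2009 and H596. ID2 was at 1.61, 0.58, 2.60 and 1.03 in the same order, and ATF3 at 1.32, 0.49, 2.82 and 1.37. The 3 genes were chosen after their values were seen.

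In RUVBL1, P296S and K265E kept nearly one ratio of read counts, 1.34, 1.35 and 1.35 in the 3 selected libraries, the narrowest range of 528 pairs of enriched alleles. In RUVBL2, G266R and D305D had ratios of 0.847, 0.842 and 0.871, the narrowest of 15 pairs. They were not the only ones: with a limit of 0.15 on the log2 range of the ratio, chosen after the values were seen, 4 RUVBL2 pairs lay within it and the other 11 ranged over 3.42 to 8.53. These 4 pairs hold 5 of the 6 enriched alleles in separate groups, G266R with D305D, and E267V with I202T and D319G. In RUVBL1, 14 pairs of 16 alleles lay within the limit, with other pairs ranging from 0.16 to 4.19, among them those of A324T and I326M with the synonymous T341T and V130V. A hypothesis is that the changes of such a pair may lie on one cDNA molecule, so that the enrichment of one of them would not speak for that change alone. A chi-square test of one ratio gave p = 0.907 for P296S and K265E and 0.394 for G266R and D305D, but the pairs were picked for their constant ratio, so these values do not decide it. The files do not link changes within a read.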
